A study of Mus musculus with 20 samples.

How the data were processed

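Messenger RNA was measured by sequencing in 20 mouse libraries that fall into 5 groups of 4. Of these, 12 were labelled ovary and form the transplant groups, in which mice received faecal microbiota from donors: young mice given microbiota of young donors (Young+YF), aged mice given microbiota of aged donors (Aged+AF) and aged mice given microbiota of young donors (Aged+YF). All 12 carry the same batch label. The other 8 were labelled oocytes A and oocytes G, with no batch label, and the labels do not expand these letters. Per the labels' protocols, total RNA was taken with magnetic beads, complementary DNA was amplified by a low-input method of the Smart-seq type, and libraries were made with a transposase. The protocol names no molecular identifiers, so amplified reads are not independent molecules, and counting intervals and detection floors given here cover counting error only. Nothing in the labels says whether the libraries of a group came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

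Each set of libraries was deposited as 1 table with expected counts, TPM and FPKM per gene and library. Per the submitters' processing notes, Bowtie2 and RSEM were used; their versions, the genome build and the gene annotation are not given in the sources used here. The expected counts are RSEM estimates of the reads per gene, per the file headers, and need not be whole. The TPM and FPKM columns hold the authors' length-scaled values, per the file headers, and were not used in the tests. The transplant table lists 17884 genes and the other table has 18381 genes, by Entrez identifier and symbol, and each table has 0 per-sample columns without a sample. A RefSeq gene table for GRCm38.p6 held 17834 and 18236 of these identifiers and served for names only. No coordinates are given, since the authors' build is not known. No symbol starting with mt- is listed in either table, so the planned share of reads from the mitochondrial genome was not run.

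Total expected counts were 24.5 to 27.9 M (1e6) in the transplant libraries, 17, 19.6, 22.7 and 23.4 M in oocytes A 1 to 4, and 23.8 to 24.4 M in oocytes G. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on expected counts rounded to whole numbers, with genes kept by filterByExpr by group (minimum count 10, minimum total 15), TMM scaling, robust dispersion and Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p under 0.05. The 12 transplant libraries shared 1 fit with 12634 genes and the 8 oocyte libraries another with 12504. Levels are counts per 1e6 (CPM) of TMM-scaled library sizes. Standard errors are the absolute log2 fold change divided by the square root of F. Fold changes were tested within a table only, since the tables were scaled separately. A gene at 0 counts in a whole group is given as a bound against 3 counts over that group, and a gene with 1 to 3 counts as the ratio of counts with its exact 95% interval (Clopper-Pearson, conditional on the sum).

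The groups compared, the tests, 20 process lists and 10 marker lists of genes, the rule for naming genes and the alternative settings were fixed before the data were examined. The rule named, per comparison, up to 10 genes per direction with the largest fold change among called genes whose 4 libraries of one group all lay above the 4 of the other, with a mean in the higher group at or above the median gene and an ordinary gene symbol; where none met it, the 5 with the smallest p. It added up to 3 members per process list by p, the 2 most abundant members per marker list, and a fixed set of genes that includes Gdf9, Zp3, Foxl2, Cyp11a1, Col1a1, Ptprc, Sod2, Gpx4, Gclm, Slc7a11, Glud1 and Sirt1; Foxl2, Col1a1 and Ptprc were too low to be tested. In the text, members of lists with nothing to report are left out. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry (limma 3.58.1), each with Benjamini-Hochberg adjustment over 28 lists. Marker lists were also summed per library in CPM and compared by an exact permutation test, two-sided, on log2 sums with 40 tests in the family; the smallest p that 4 against 4 libraries can give is 0.0286. With genes at 0 to 3 counts in a group set to that bound, 0 of the 112 list medians moved. Log2 CPM for the covariance of fold changes, list levels per library and trends used a prior count of 2. Principal components and the correlations between replicate numbers were taken on the log2 of CPM plus a small constant.

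A check of each library against a weighted sum of the other 3 of its group, over genes with a fitted count of at least 20, found that oocytes G 4 differed from a weighted sum of oocytes G 1 to 3 by little more than the counting noise. Means of oocytes G are therefore given over libraries 1 to 3, while the fixed test keeps all 4, with its count without library 4 beside it. No 2 libraries hold identical count columns.

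The fit was tested on simulated counts, drawn for each real gene from its mean over the libraries of its table, its dispersion and the library sizes, with 50 genes above the median level changed at each of 4 sizes. In Aged+AF against Young+YF it called 12% of genes changed 2-fold, 74% at 4-fold and 90% at 8-fold. The figures were 2%, 68% and 96% for Aged+YF against Aged+AF, 6%, 70% and 90% for Aged+YF against Young+YF, and 0%, 32% and 86% for oocytes G against A. Among unchanged genes it called 8, 8, 6 and 2. Each gene was drawn independently, without the shared movement of genes within a library, so these figures can overstate recovery in the real libraries. Alternatives were DESeq2 size factors, no filter, a filter of 50 counts in 4 libraries, DESeq2's Wald test (1.42.0), limma-voom with and without sample weights, the replicate number as a block, fits of only the groups compared, and each library left out in turn. Genes with near-identical copies or processed pseudogenes (ribosomal proteins, Mt1 and Mt2, the Hsd3b1 family, Aldoa, Tpi1, Ldha, Tuba1a, Gpx4) can share reads with them, and their counts depend on how these reads were divided.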

Results

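The study concerns glutamic acid controlled by gut bacteria and its bearing on oocytes of older females. Messenger RNA was sequenced from 12 mouse libraries labelled ovary and 8 labelled oocytes. The first 12 fall into 3 groups of 4: young mice that received faecal microbiota of young donors (Young+YF), aged mice that received that of aged donors (Aged+AF) and aged mice that received that of young donors (Aged+YF). The comparisons among them ask what differs between aged and young recipients and whether microbiota of young donors moves aged recipients towards the young ones. Between Aged+AF and Young+YF, recipient age and donor age change together, and no young group received aged microbiota. The other 8 are 4 libraries each of oocytes A and oocytes G, letters that the labels do not expand. Depth was 24.5 to 27.9 M (1e6) counts in the transplant libraries and 23.8 to 24.4 M in oocytes G. Oocytes A 1 to 4 had 17, 19.6, 22.7 and 23.4 M.

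Oocyte transcripts dominated the marker genes of both tables, including the libraries labelled ovary, whose protocol says that RNA was taken from ovary and names no part of it. The 30 genes of the oocyte list, such as Gdf9 (a growth factor secreted by oocytes), summed to 85500 ± 7770 CPM (SD, n = 4) in Young+YF, 73300 ± 8380 (SD, n = 4) in Aged+AF and 88300 ± 31800 (SD, n = 4) in Aged+YF. The endothelial list summed to 42.8 ± 6.40 CPM in Young+YF and the smooth muscle list to 46.0 ± 5.89 (SD, n = 4 each). Genes of theca and luteal cells, the steroid-producing cells of the ovary, summed to 502 ± 332 CPM in Aged+AF, with libraries from 156 to 935, against 135 ± 54.3 in Young+YF and 110 ± 40.4 in Aged+YF (SD, n = 4 each). The sum of leukocyte and macrophage genes ran the other way, at 27.3 ± 6.55 CPM in Aged+AF and 66.4 ± 12.9 in Young+YF (SD, n = 4 each), while Aged+YF 4 alone reached 279. Much of the gap between Aged+AF and Young+YF lay in H2-Aa, at 11.6 ± 5.05 against 46.5 ± 11.8 CPM (SD, n = 4 each, adjusted p = 0.101). Of the 8 immune genes tested there, edgeR called 0. Surface epithelium genes summed to 29.4 ± 29.4 CPM in Aged+AF, 5.97 ± 0.504 in Young+YF and 3.54 ± 1.5 in Aged+YF (SD, n = 4 each). In the other table, which was scaled separately, the oocyte list summed to 20600, 28600, 64500 and 73700 CPM in oocytes A 1 to 4 and to 71600 ± 11000 (SD, n = 3) in oocytes G 1 to 3. Granulosa genes summed to 68.1, 81.1, 439 and 596 CPM in oocytes A 1 to 4 and to 689 ± 39.8 in oocytes G 1 to 3 (SD, n = 3). No difference in list sums between groups passed adjustment over 40 exact permutation tests, two-sided, of which the smallest p of 0.0286 gave an adjusted p of 0.163. Since 4 against 4 libraries can give no smaller p, no list could pass on its own, however large its difference. Stroma, immune and surface epithelium genes reached it in Aged+AF against Young+YF, and surface epithelium genes in both comparisons of Aged+YF. So did granulosa and theca and luteal genes in oocytes G against A, with oocytes G 4 counted.

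**Figure D1:**
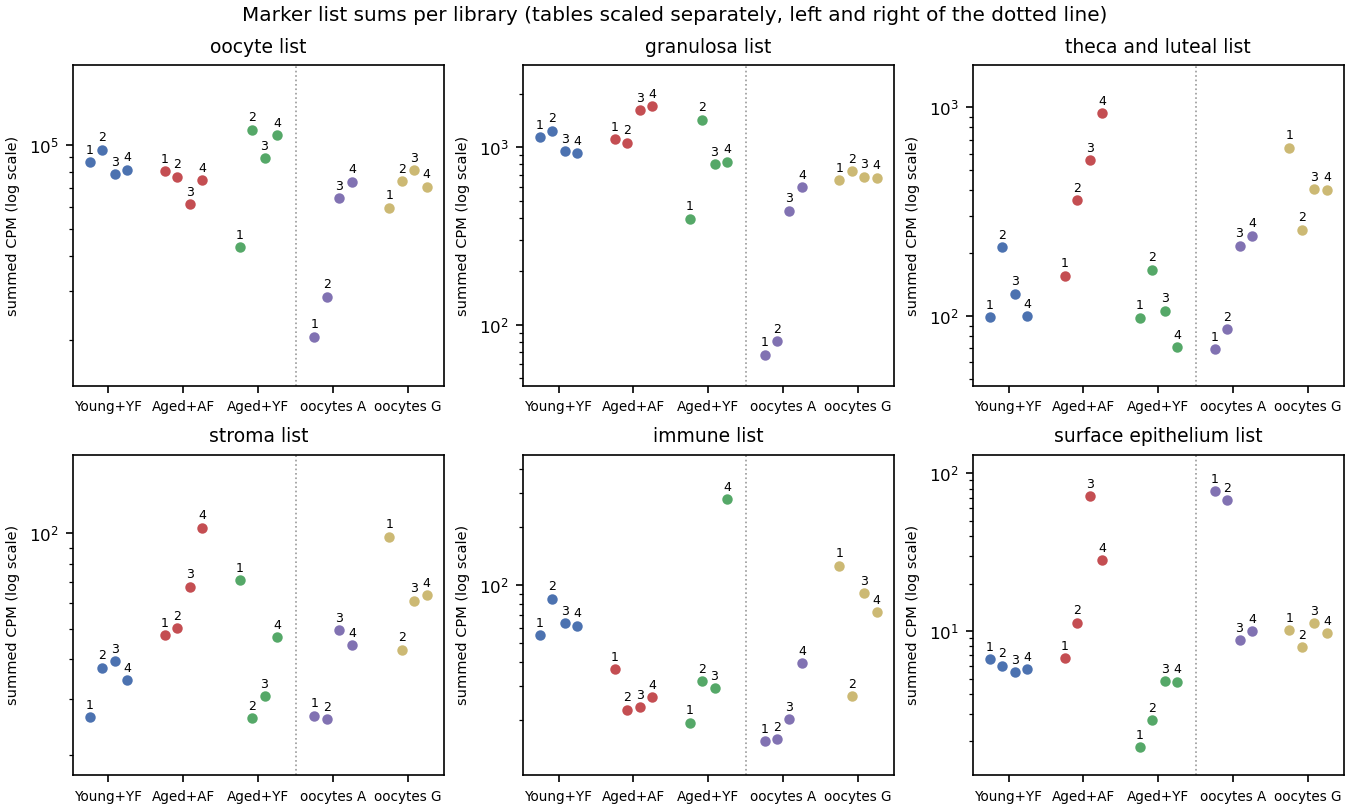
Summed level in CPM (log scale) of 6 marker lists in each library; points are libraries numbered 1 to 4 and the dotted line parts the tables, which were scaled separately. Theca and luteal genes lie between 156 and 935 CPM in Aged+AF and between 71.0 and 167 in Aged+YF, and oocytes A 1 and 2 lie below the other oocyte libraries in the oocyte list.

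Several genes of steroid-producing and other follicle cells were higher in Aged+AF than in Young+YF. Hsd3b1 (Entrez 15492), an enzyme of progesterone synthesis, stood at 158 ± 136 CPM (SD, n = 4) against 1.62 ± 2.94 (SD, n = 4), a log2 fold change of 6.60 ± 1.54 (SE, adjusted p = 0.0403). Cyp11a1 (Entrez 13070), the enzyme of the first step of steroid synthesis, stood at 12.8 ± 9.70 CPM against 1.59 ± 0.692 (SD, n = 4 each, log2 fold change 3.01 ± 0.70 SE, adjusted p = 0.0393). Exd1 (Entrez 241624), which takes part in piRNA production, was lower, at 3.08 ± 1.04 CPM against 23.7 ± 4.27 (SD, n = 4 each, log2 fold change -2.94 ± 0.37 SE, adjusted p = 0.00298). In all, 282 of 12634 genes tested differed at an adjusted p under 0.05, 248 higher and 34 lower in Aged+AF. In 1715 genes (13.6%) the libraries of the groups did not overlap, where chance gives 2.9%.

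Of the 9 theca and luteal genes tested, 4 rose, and 6 rose when adjusted over the list alone. Their median log2 fold change was 3.01 (camera adjusted p = 2.79e-06, and adjusted p = 0.329 with an estimated correlation, fry adjusted p = 0.0566). Of the 11 granulosa genes, 3 rose, 7 adjusted over the list alone, with a median of 4.13 (camera adjusted p = 0.000888, and adjusted p = 0.339 with an estimated correlation, fry adjusted p = 0.0714). The most abundant granulosa gene, Serpine2, a protease inhibitor, stood at 969 ± 191 against 974 ± 132 CPM (SD, n = 4 each, log2 fold change -0.01 ± 0.36 SE). The granulosa list summed to 1370 ± 337 CPM in Aged+AF and 1060 ± 151 in Young+YF (SD, n = 4 each, p = 0.2 by exact permutation, two-sided). Among the largest increases in abundant genes was Thbs1, a matrix glycoprotein, at 33.3 ± 11.9 CPM against 0.203 ± 0.263 (SD, n = 4 each, log2 fold change 7.32 ± 1.54 SE). Sfrp4, a secreted Wnt inhibitor, stood at 12.4 ± 10.8 against 0.0493 ± 0.0986 CPM, and Vcan, the proteoglycan versican, at 21.4 ± 21.6 against 0.325 ± 0.573 CPM (SD, n = 4 each). The log2 fold changes of Procr, Nts, Tuba1a, Mt1, Mt2 and Gcsh were 9.08, 7.23, 6.67, 6.65, 5.31 and 5.18. In the stroma list Sparc rose, as did the keratin Krt8 in the surface epithelium list, by 3.23 ± 0.77 and 4.74 ± 1.15 on the log2 scale (SE). In Young+YF, library 2 stood above the other 3 in several of these genes, with 6.04 CPM of Hsd3b1 where the others had 0.13 to 0.179.

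Transcripts of some genes of the protein synthesis and energy machinery were higher as well. Of 76 cytoplasmic ribosomal protein genes, 32 rose, and 56 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 1.79 (camera adjusted p = 1.06e-34, and adjusted p = 0.329 with an estimated correlation). Rpsa stood at 25.2 ± 15.1 CPM against 2.60 ± 0.604 (SD, n = 4 each, log2 fold change 3.28 ± 0.55 SE, adjusted p = 0.0195), and Rps18 was higher by 3.20 on the log2 scale. Of 77 nuclear-encoded subunits of the respiratory complexes, 12 rose, 33 adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.73e-13, and adjusted p = 0.347 with an estimated correlation). Among them were Cox7b, Ndufs8 and Ndufa12, with log2 fold changes of 3.18, 3.22 and 3.00. Of 33 genes of glycolysis and the TCA cycle, 4 rose, among them Ldha at 53.3 ± 54.5 CPM against 1.18 ± 1.56 (SD, n = 4 each), Tpi1 and Aldoa. Adjusted over the list alone 15 rose and 1 fell (median 0.86, camera adjusted p = 0.000448, and adjusted p = 0.347 with an estimated correlation). In cholesterol synthesis 2 of 23 genes rose, 5 adjusted over the list alone, among them Fdps at 92.5 ± 71.1 CPM against 7.88 ± 2.38 (SD, n = 4 each) and Ebp (camera adjusted p = 0.00517, and adjusted p = 0.329 with an estimated correlation). Gpx4, a glutathione peroxidase that removes lipid peroxides, Casp6, an effector caspase, and Scd1, a fatty acid desaturase, rose by 2.59 ± 0.63, 3.96 ± 0.71 and 6.41 ± 1.09 on the log2 scale (SE).

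Glutamate and glutamine genes did not pass. Of 27 genes of glutamate and glutamine synthesis, breakdown and transport, edgeR called 0 in Aged+AF against Young+YF, 3 had an unadjusted p under 0.05, DESeq2's Wald test called 0 and limma-voom 1. The median and mean log2 fold changes of the list were 0.04 and 0.42, and camera placed it lower with an adjusted p of 0.811. Slc38a2, a glutamine transporter, stood at 7.68 ± 4.26 CPM against 0.272 ± 0.372 (SD, n = 4 each, log2 fold change 4.8 ± 1.46 SE, adjusted p = 0.105). Glud1, the mitochondrial glutamate dehydrogenase, stood at 29.3 ± 4.61 CPM against 34.9 ± 11.7 (SD, n = 4 each, adjusted p = 0.833). The mitochondrial glutamate carrier Slc25a22 had a log2 fold change of 1.73 ± 0.65 (SE, adjusted p = 0.202), and Aged+AF 3 alone held 23.9 CPM of Slc25a22. Log2 fold changes of Gdf9, Zp3, Sod2, Gclm, Slc7a11 and Sirt1 were -0.12, 0.04, -0.22, 0.19, 0.05 and -0.45, with adjusted p from 0.785 to 0.985.

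Among genes lower in Aged+AF, Cdc5l, a splicing factor, stood at 9.63 ± 3.78 CPM against 358 ± 54.0, and Dbt, a subunit of the enzyme that breaks down branched-chain amino acids, at 12.8 ± 5.09 against 258 ± 31.7 (SD, n = 4 each, log2 fold changes -5.22 ± 0.83 and -4.34 ± 0.82 SE). Kcng2, a potassium channel subunit, stood at 0.468 ± 0.541 CPM against 66.8 ± 15.7 (SD, n = 4 each). Shmt1, a serine hydroxymethyltransferase of folate metabolism, was 620 times as abundant in Young+YF (95% counting interval 212 to 3010), where it stood at 16.8 ± 5.48 CPM (SD, n = 4). Log2 fold changes of Slc14a1, Tlr8, Pigh, Hnrnpa0 and Ly6g6e were -5.68, -3.24, -3.20, -3.14 and -3.13, and that of Hspb1, a small heat shock protein, was -2.24. DNA repair genes had a median of -0.20 over 33 members (camera adjusted p = 0.021, and adjusted p = 0.329 with an estimated correlation). Of these edgeR called 0, and 2 had an unadjusted p under 0.05, 1 higher and 1 lower in Aged+AF. The Wald test called 1, which was higher in Aged+AF, and limma-voom called 0. DNA repair was the list that fry, which tests whether a list moves to either side, called at an adjusted p of 0.0313.

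The count of 282 depended on single libraries. It was 6, 80, 12 and 5 without Young+YF 1 to 4, and 438, 8 and 13 without Aged+AF 1, 2 and 4. Of the 41 called genes that the naming rule covers, 1 (Exd1) passed in all 8 fits with a library left out. DESeq2's Wald test called 848 genes, limma-voom with sample weights 1722, a fit of these groups alone 651, and a fit without Aged+AF 3 and 4, chosen after seeing the data for their theca and luteal sums of 556 and 935 CPM, 19 genes and 5 lists in place of 13.

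**Figure D2:**
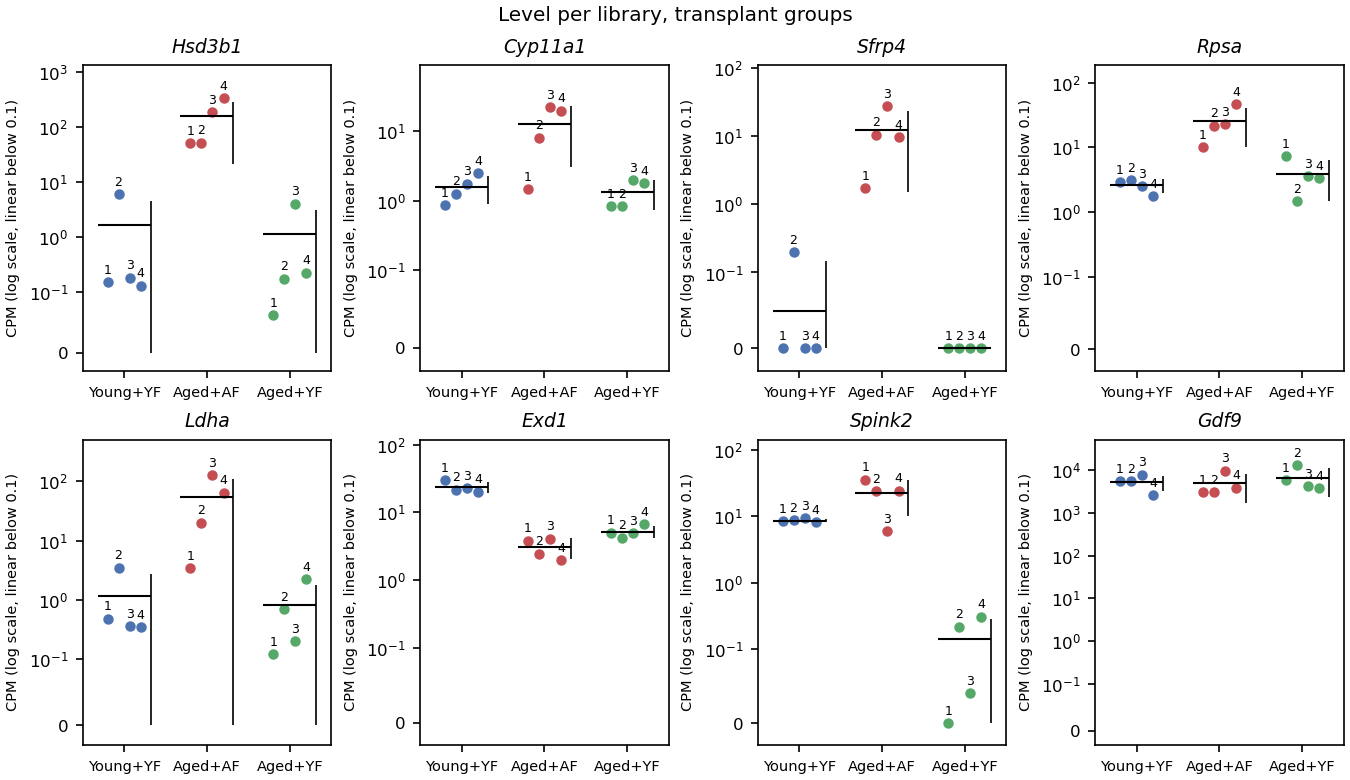
Level in CPM (log scale, linear below 0.1) of 8 genes in the transplant libraries; points are libraries numbered 1 to 4, horizontal lines are means and vertical lines 1 SD to either side, cut off at 0. Hsd3b1 lies between 51.7 and 337 CPM in Aged+AF and between 0.061 and 6.04 in the other libraries, and Exd1 lies at 20.2 CPM or above in Young+YF and at 6.64 or below in both aged groups.

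Aged recipients of young microbiota had lower levels of several follicle cell genes than aged recipients of aged microbiota. Hsd3b1 stood at 1.12 ± 1.93 CPM in Aged+YF against 158 ± 136 in Aged+AF (SD, n = 4 each, log2 fold change -7.14 ± 1.59 SE, adjusted p = 0.0467), and Cyp11a1 at 1.35 ± 0.607 against 12.8 ± 9.70 (SD, n = 4 each, log2 fold change -3.24 ± 0.71 SE, adjusted p = 0.0425). Inhba, an activin subunit made by granulosa cells, stood at 0.138 ± 0.256 CPM against 24.2 ± 11.9, and Spink2 (Entrez 69982), a protease inhibitor, at 0.142 ± 0.146 against 22.5 ± 12.3 (SD, n = 4 each, log2 fold changes -7.41 ± 1.22 and -7.34 ± 0.83 SE, adjusted p = 0.0177 and 0.00145). Sp140, a nuclear body protein, was higher, at 214 ± 50.3 CPM against 47.8 ± 28.6 (SD, n = 4 each, log2 fold change 2.16 ± 0.41 SE, adjusted p = 0.0341). Of 12634 genes, 159 differed, 10 higher and 149 lower in Aged+YF. The libraries of the groups did not overlap in 954 genes (7.6%, against 2.9% by chance).

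Of the 9 theca and luteal genes, 3 fell, 8 adjusted over the list alone, with a median log2 fold change of -4.03 (camera adjusted p = 2.73e-08, and adjusted p = 0.156 with an estimated correlation). Of 11 granulosa genes 2 fell, 6 adjusted over the list alone (median -3.97, camera adjusted p = 1.45e-06, and adjusted p = 0.156 with an estimated correlation). The surface epithelium list moved down too (camera adjusted p = 0.00187, and adjusted p = 0.156 with an estimated correlation), with Krt8 at 0.0763 ± 0.103 CPM against 17.1 ± 23.8 (SD, n = 4 each). The granulosa list summed to 865 ± 427 CPM in Aged+YF and 1370 ± 337 in Aged+AF (SD, n = 4 each, p = 0.114 by exact permutation, two-sided). Serpine2 stood at 781 ± 424 against 969 ± 191 CPM (SD, n = 4 each, adjusted p = 0.809). Sfrp4 and Mgp, a matrix protein that inhibits calcification, had 0 counts in Aged+YF, which puts them at least 427-fold and 411-fold lower than in Aged+AF against 3 counts over the group. Scd1 was 967 times as abundant in Aged+AF (95% counting interval 173 to 38200). Log2 fold changes of Tmem86a, Hs3st1, Crim1 and Sparc were -8.67, -8.09, -6.84 and -3.87. In Aged+YF, library 3 alone held most of what remained of several of these genes, with 4.01 CPM of Hsd3b1 and 0.521 of Inhba.

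Ribosomal protein genes had a median log2 fold change of -1.24, and 3 of 76 fell, 39 adjusted over the list alone (camera adjusted p = 4.13e-18, and adjusted p = 0.315 with an estimated correlation). Rpsa and Rps18 were among them, with log2 fold changes of -2.68 ± 0.53 and -2.88 ± 0.58 (SE). Of 77 respiratory complex subunits 8 fell, 19 adjusted over the list alone (median -0.68, camera adjusted p = 2.73e-08, and adjusted p = 0.397 with an estimated correlation), among them Ndufb10 and Atp5j by -2.87 ± 0.57 and -3.55 ± 0.78 (SE). In glycolysis and the TCA cycle 3 of 33 genes fell, 12 adjusted over the list alone, namely Ldha, Tpi1 and Aldoa by -6.06, -4.08 and -3.61 on the log2 scale (camera adjusted p = 0.0018, and adjusted p = 0.35 with an estimated correlation). In cholesterol synthesis 2 of 23 genes fell, 7 adjusted over the list alone, with Fdps at 7.60 ± 5.41 CPM against 92.5 ± 71.1 (SD, n = 4 each, camera adjusted p = 0.00124, and adjusted p = 0.241 with an estimated correlation). Casp6 fell by 3.51 on the log2 scale. Oocyte genes had a median of 0.29 (camera adjusted p = 0.00119, and adjusted p = 0.315 with an estimated correlation). Their sum was 43100, 113000, 89200 and 108000 CPM in Aged+YF 1 to 4 and 61200 to 80500 in Aged+AF, with p = 0.629 by exact permutation, two-sided. DNA repair genes had a median of 0.32 (camera adjusted p = 0.00418, and adjusted p = 0.141 with an estimated correlation). Fry called 8 of 28 lists: DNA repair higher (adjusted p = 0.014), granulosa, theca and luteal, surface epithelium and cholesterol genes lower (0.0199 each), and stroma, antioxidant and apoptosis genes lower (0.0464 each).

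Of the genes higher in Aged+YF, Stom, a membrane protein, stood at 38.4 ± 14.4 CPM against 6.77 ± 4.38, and Eif2ak3, the stress kinase PERK of the endoplasmic reticulum, at 31.4 ± 10.2 against 7.62 ± 2.05 (SD, n = 4 each, log2 fold changes 2.5 ± 0.5 and 2.04 ± 0.38 SE). Log2 fold changes of Polr1a, Slc15a2, Abcc10, Cdh2 and Cgnl1 were 2.01, 1.94, 1.66, 1.55 and 1.28. Of the 27 glutamate and glutamine genes edgeR called 0 in this comparison, 2 had an unadjusted p under 0.05, the Wald test called 0 and limma-voom 1. The median of the list was 0.02 and its mean -0.19, and camera placed it higher (adjusted p = 0.809). Slc38a2 stood at 0.494 ± 0.883 CPM against 7.68 ± 4.26 (SD, n = 4 each, log2 fold change -3.97 ± 1.40 SE, adjusted p = 0.187) and Glud1 at 34.3 ± 11 against 29.3 ± 4.61 (SD, n = 4 each, adjusted p = 0.865). Gpx4 had a log2 fold change of -2.49 ± 0.63 (SE, adjusted p = 0.0596), and those of Gdf9, Zp3, Sod2, Gclm, Slc7a11 and Sirt1 lay between -0.12 and 0.44.

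The count of 159 was 379, 26, 55 and 13 without Aged+AF 1 to 4, 17 and 4 without Aged+YF 1 and 2, and 36 without Young+YF 1, which enters through the shared fit. Of 37 called genes under the naming rule, 1 (Spink2) passed in all 8 such fits. It was 720 with the Wald test, 295 with limma-voom, 676 with sample weights, 32 with the stricter filter, 68 in a fit of these groups alone, and 8 without Aged+AF 3 and 4, chosen after seeing the data, where 7 lists in place of 16 were called.

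**Figure D3:**
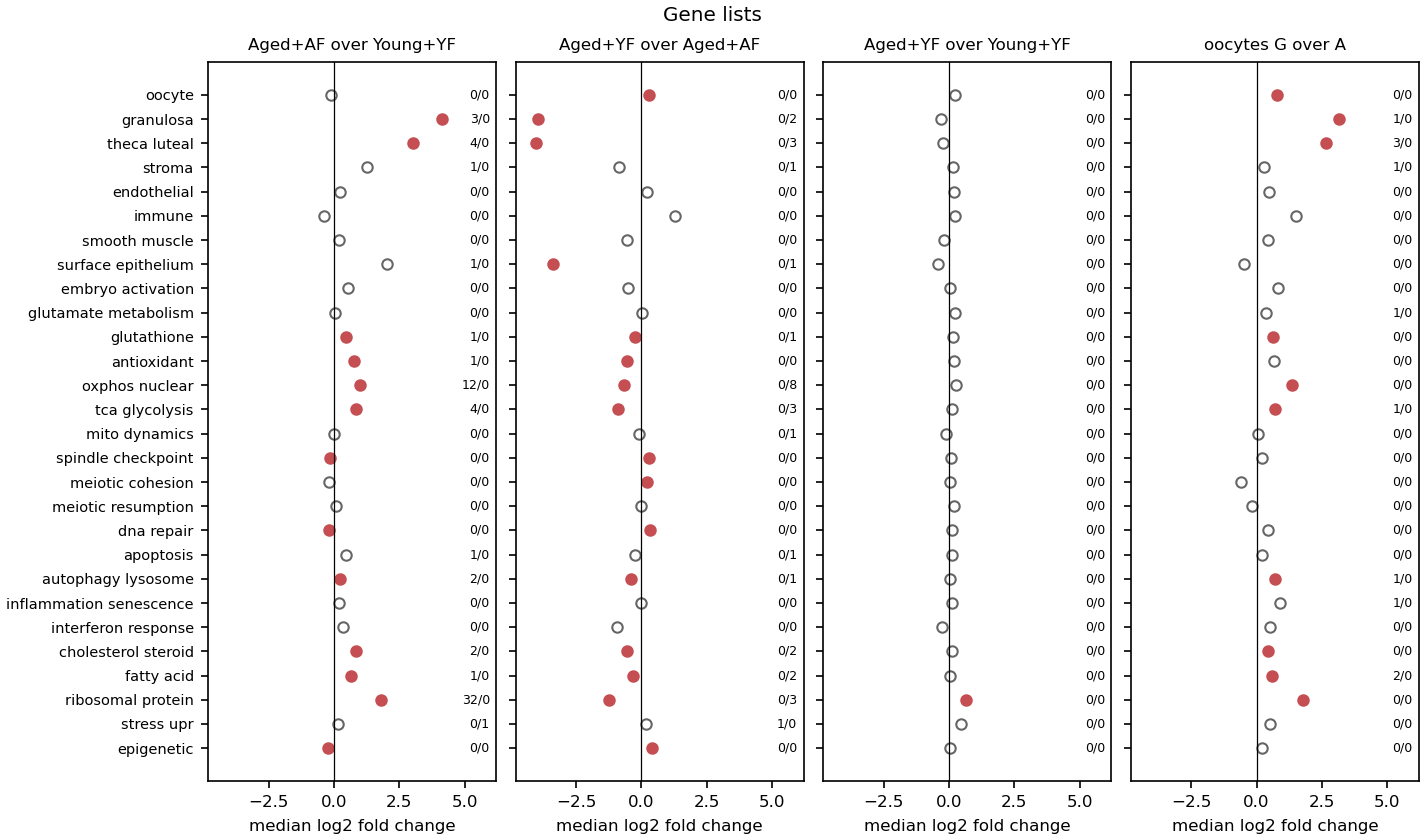
Median log2 fold change of 28 gene lists in 4 comparisons; red dots passed camera at a preset correlation of 0.01 (none pass with an estimated correlation), and the numbers give the members called higher and lower. Ribosomal protein genes have medians of 1.79, -1.24, 0.65 and 1.76 from left to right.

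Of the 248 genes higher in Aged+AF than in Young+YF, 84 were lower again in Aged+YF than in Aged+AF, and 4 of the 34 lower genes were higher again. These 88 genes include Hsd3b1, Cyp11a1, Sfrp4, Vcan, Krt8, Sparc, Fdps, Ldha, Tpi1, Aldoa, Rpsa, Rps18, Casp6, Inhba and Scd1 in the first direction and Cdc5l, Stom, Abcc10 and Cdh2 in the second. Both comparisons use the Aged+AF libraries. Independent lists would share 2.92 and 0.0269 genes, and 20 simulated sets of unchanged groups shared at most 0. The simulation drew each gene independently, without the shared movement of genes within a library, so it can understate what chance gives. With different Aged+AF libraries in each comparison, 2 and 2, the count was between 2 and 7 in the 6 ways to divide them, against 0.0535 for independent lists of that size. Across 12634 genes, which are not independent replicates, the fold changes of Aged+YF over Aged+AF and of Young+YF over Aged+AF had a covariance of 0.958 (log2 squared) and a correlation of 0.768. Unchanged groups, simulated in the same way, gave a covariance of 0.225 and a correlation of 0.499, so the difference in covariance was 0.733. The covariance was the highest of the 70 ways to label the 8 aged libraries, with a p of 0.0143 by exact permutation, one-sided, which is the smallest p they can give; the median of all labellings was 0.255. With the Aged+AF libraries divided it averaged 0.741 (0.672 to 0.79). The count of 88 was 218, 5, 43 and 4 without Aged+AF 1 to 4, 15 and 3 without Aged+YF 1 and 2, 4, 40, 8 and 2 without Young+YF 1 to 4, and 6 without Aged+AF 3 and 4.

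**Figure D4:**
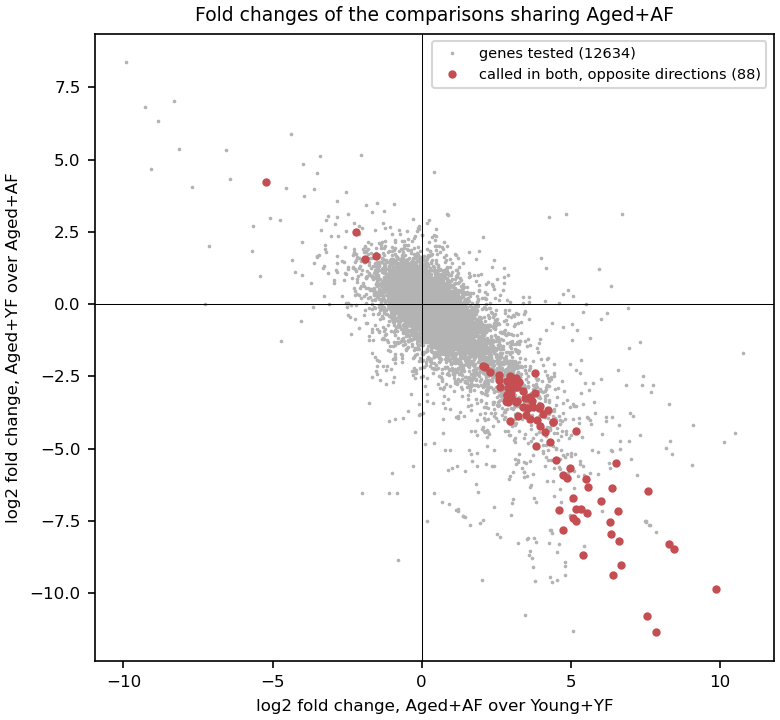
Log2 fold change of each tested gene in Aged+YF over Aged+AF (vertical) against Aged+AF over Young+YF (horizontal), with the 88 genes called in both and in opposite directions marked. Since Aged+AF enters both axes with opposite signs, unchanged groups also give a falling cloud. Simulated with genes drawn independently, its correlation was 0.499 in size, against 0.768 here.

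Between aged and young recipients that both received young microbiota, few genes differed. Sp140 stood at 214 ± 50.3 CPM in Aged+YF against 28.4 ± 2.17 in Young+YF (SD, n = 4 each, log2 fold change 2.91 ± 0.42 SE, adjusted p = 0.0133). Olfm1, a secreted glycoprotein, stood at 130 ± 19.4 against 37.4 ± 6.52 CPM, and Agtpbp1, a carboxypeptidase that removes glutamate from tubulin tails, at 319 ± 136 against 83.1 ± 10.8 (SD, n = 4 each, adjusted p = 0.0359 and 0.0374). Spink2 was lower, at 0.142 ± 0.146 against 8.62 ± 0.482 CPM, and so was Exd1, at 5.18 ± 1.03 against 23.7 ± 4.27 (SD, n = 4 each, log2 fold changes -5.96 ± 0.80 and -2.19 ± 0.36 SE, adjusted p = 0.00736 and 0.0343). In all 14 of 12634 genes differed, 10 higher and 4 lower, with Rufy2 and Amer1 at log2 fold changes of 2.5 and -2.80. Libraries of the groups did not overlap in 662 genes (5.2%, against 2.9% by chance). Hsd3b1 and Cyp11a1, which differed between Aged+AF and each of these groups, stood at 1.12 ± 1.93 and 1.35 ± 0.607 CPM in Aged+YF and at 1.62 ± 2.94 and 1.59 ± 0.692 in Young+YF (SD, n = 4 each). Of the 28 lists camera called the ribosomal protein genes, with a median of 0.65 (adjusted p = 3.5e-06, and adjusted p = 0.923 with an estimated correlation). Without Aged+YF 4 that adjusted p was 0.508. Of 27 glutamate and glutamine genes edgeR called 0, 1 had an unadjusted p under 0.05, and the Wald test and limma-voom called 0 each. Log2 fold changes of Sirt1, Sod2, Cyp11a1, Glud1, Gpx4, Zp3, Slc7a11, Gdf9 and Gclm ran from -0.45 to 0.48, with adjusted p of 0.967 or more. The count of 14 was 2, 4, 4 and 4 without Young+YF 1 to 4 and 24, 0, 4 and 53 without Aged+YF 1 to 4. For the 0, 1174 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.0543. None of the 7 called genes under the naming rule passed in all 8 fits. The Wald test called 57 genes higher and 34 lower, limma-voom 12 and 20, sample weights 159 and 182, and the fit without Aged+YF 4 20 and 33, so the balance of directions was not stable.

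Oocytes G held more transcript of several luteal and follicle cell genes than oocytes A. Spp1 (Entrez 20750), the secreted phosphoprotein osteopontin, stood at 550 ± 559 CPM in oocytes G 1 to 3 (SD, n = 3) against 0.323 ± 0.122 in oocytes A (SD, n = 4), a log2 fold change of 10.66 ± 0.90 (SE, adjusted p = 0.00774). Akr1c18 (Entrez 105349), the luteal enzyme that inactivates progesterone, stood at 27.6 ± 19.7 CPM (SD, n = 3) and was 2200 times as abundant as in oocytes A (95% counting interval 395 to 86900, adjusted p = 0.00774). Timp1, an inhibitor of matrix metalloproteinases, stood at 50.4 ± 48.2 CPM against 0.0674 ± 0.0858, and Inha, the alpha subunit of inhibin from granulosa cells, at 26.7 ± 18.9 against 0.112 ± 0.171 (SD, n = 3 and 4, log2 fold changes 9.44 ± 1.12 and 7.68 ± 0.95 SE, adjusted p = 0.0169 and 0.0208). Of 12504 genes 45 differed, 44 higher and 1 lower in oocytes G, and 5 differed without oocytes G 4. Unless stated, p-values of genes and lists in this comparison count oocytes G 4 as an independent library, which it may not be. Timp1 and Inha passed in 4 each of the 8 fits with a library left out. Libraries of the groups did not overlap in 2326 genes, and in 2388 (19.1%, against 5.7% by chance) without oocytes G 4.

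Of 9 theca and luteal genes 3 rose, 6 adjusted over the list alone (median 2.66, camera adjusted p = 5.16e-09, and adjusted p = 0.176 with an estimated correlation). Of 11 granulosa genes 1 rose, and 6 rose and 1 fell adjusted over the list alone (median 3.17, camera adjusted p = 0.000018, and adjusted p = 0.222 with an estimated correlation). The theca and luteal list summed to 435 ± 193 CPM in oocytes G 1 to 3 (SD, n = 3) and 154 ± 88.6 in oocytes A (SD, n = 4). Globin and other red cell genes summed to 377, 0.0394, 0.131 and 101 CPM in oocytes G 1 to 4, against 0.225 or less in oocytes A (p = 0.2 by exact permutation, two-sided). Leukocyte and macrophage genes summed to 81.0 ± 50.2 CPM in oocytes G 1 to 3 (SD, n = 3) and 22.8 ± 11.2 in oocytes A (SD, n = 4; fry adjusted p = 0.0373, camera adjusted p = 0.0828). Tnfaip6, a protein of the cumulus matrix, Tmem86a, Alcam, Rgcc and Nupr1 had log2 fold changes of 7.83, 8.03, 7.39, 6.89 and 6.87, and Sparc one of 3.39 ± 0.50 (SE, adjusted p = 0.0401). Of 27 fatty acid genes 2 rose, 3 adjusted over the list alone, the desaturases Scd2, by 6.91 ± 1.01 on the log2 scale (SE), and Scd1, 120 times as abundant (95% counting interval 40.9 to 586; camera adjusted p = 0.0311, and adjusted p = 0.235 with an estimated correlation). The glycolytic enolase Eno1 stood at 22.4 ± 7.01 CPM against 4.20 ± 0.882 (SD, n = 3 and 4, adjusted p = 0.0245), the 1 called of 33 genes of glycolysis and the TCA cycle (camera adjusted p = 0.0063, and adjusted p = 0.176 with an estimated correlation). The calls in this paragraph come from the fit with oocytes G 4. Eno1, Sparc, Scd1 and Scd2 passed in 3, 2, 2 and 2 of the 8 fits with a library left out.

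Ribosomal protein genes had a median log2 fold change of 1.76. Of these 76 genes edgeR called 0 over all genes, 71 rose adjusted over the list alone, 71 had an unadjusted p under 0.05, and the Wald test and limma-voom called 61 and 0 (camera adjusted p = 1.13e-28, and adjusted p = 0.235 with an estimated correlation). Rpl19 had a log2 fold change of 1.82 ± 0.32 (SE, adjusted p = 0.0518). Of 78 respiratory complex subunits edgeR called 0 over all genes, 20 rose adjusted over the list alone, 43 had an unadjusted p under 0.05, and the Wald test and limma-voom called 30 and 0 (median 1.36, camera adjusted p = 9.09e-16, and adjusted p = 0.33 with an estimated correlation). Fry called these lists at adjusted p of 0.00805 and 0.0261. The respiratory list varied within oocytes A: its median log2 level, relative to the mean of all 8 libraries, was -1.74, -1.91, -0.01 and 0.23 in oocytes A 1 to 4 and 1.31, 0.44, 0.87 and 0.85 in oocytes G 1 to 4. That of the ribosomal list was -1.11, -1.11, -0.88 and -0.29 in oocytes A and 1.73, 0.28, 0.73 and 0.95 in oocytes G. Oocyte genes had a median of 0.79 (camera adjusted p = 0.00236, and adjusted p = 0.578 with an estimated correlation), with oocytes A 1 and 2 below the other libraries in the sum of the list.

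Of the 27 glutamate and glutamine genes 1 rose, 2 adjusted over the list alone. Slc38a2 was 355 times as abundant in oocytes G as in oocytes A (95% counting interval 63.3 to 14000, adjusted p = 0.0334), at 4.81 ± 4.99 CPM in oocytes G 1 to 3 (SD, n = 3), where library 1 held 10.5 and the others of the group 1.26 to 2.81. That call comes from the fit with oocytes G 4, and it passed in 2 of the 8 fits with a library left out. The glutamate transporter Slc1a1 and the aspartate aminotransferase Got1 had log2 fold changes of 2.23 ± 0.55 and 0.95 ± 0.33 (SE, adjusted p = 0.0861 and 0.123). The list had a median of 0.36, a camera adjusted p of 0.169 and a fry adjusted p of 0.00475, in a comparison where fry called 15 of 28 lists, all higher. These tests count oocytes G 4 as independent, and fry was not run on the lists without it. Camera, at the preset correlation, called 11 lists without it and 10 with it. Glud1 had a log2 fold change of -0.37 (adjusted p = 0.398). Mgst1, Atp5j, Fdps, Gpx4, Cyp11a1, Zp3 and Gdf9 had log2 fold changes of 6.54, 2.66, 3.76, 2.31, 2.02, 1.17 and 1.55 that did not pass (adjusted p from 0.0577 to 0.345), and Sod2, Slc7a11, Gclm and Sirt1 lay between -0.12 and 0.62. The gene lower in oocytes G was A26c3, whose level lay below the median gene and which is therefore named here as the smallest p in that direction, with a log2 fold change of -1.91 ± 0.31 (SE, adjusted p = 0.0425). Smad5 and Vmn2r25, among the next smallest p in that direction, did not pass, with log2 fold changes of -1.69 and -2.37 (adjusted p = 0.0577 and 0.0673).

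The count of 45 was 17, 3, 4 and 2740 without oocytes A 1 to 4 and 7, 7 and 5 without oocytes G 1, 3 and 4, and the 2740 were 928 higher and 1812 lower. Spp1 and Akr1c18, 2 of 16 called genes under the naming rule, passed in all 8 such fits. The Wald test called 2061 genes (710 higher and 1351 lower), sample weights 1333 (725 and 608), limma-voom 16, no filter 80 and the stricter filter 14, and a fit without oocytes A 1 and 2 and oocytes G 4, chosen after seeing the data, 19. Without oocytes G 4, 2 of 35 splits of the libraries called as many as the 5 genes of the real split.

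**Figure D5:**
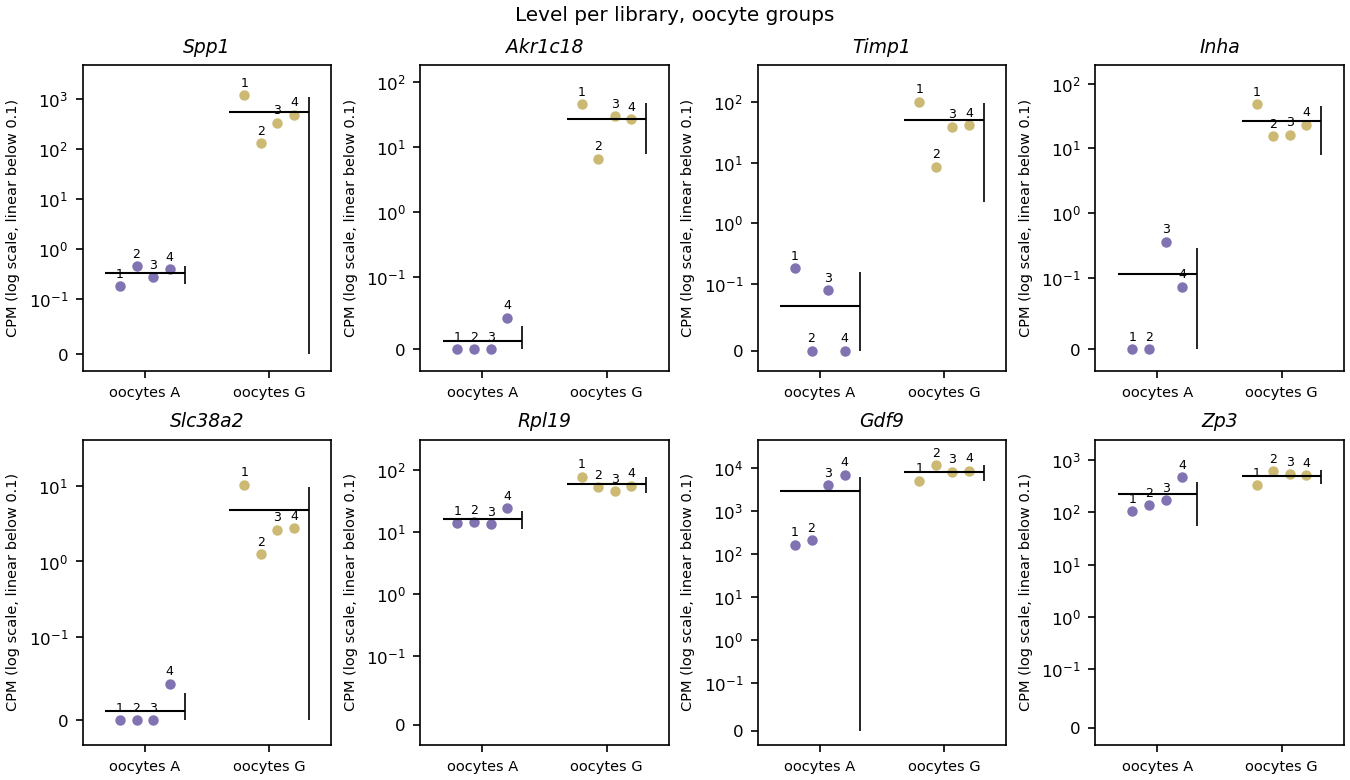
Level in CPM (log scale, linear below 0.1) of 8 genes in the oocyte libraries; points are libraries numbered 1 to 4, horizontal lines are means and vertical lines 1 SD to either side, cut off at 0, over libraries 1 to 3 for oocytes G. Spp1 lies at 0.45 CPM or below in oocytes A and between 130 and 1184 in oocytes G.

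The genes called among the transplant groups were also followed in the oocyte table. Of the 248 genes higher in Aged+AF than in Young+YF, 210 were tested there, with 183 of them higher in oocytes G than in oocytes A and a median log2 fold change of 1.99. Of these, 14 were called higher, where independent lists would share 0.74; without oocytes G 4, 2 were among the 5 genes called in all, against 0.08. Of the 149 genes lower in Aged+YF than in Aged+AF, 119 were tested, 106 were higher in oocytes G, with a median of 2.09, and 11 were called, where independent lists would share 0.42 (2 of 5, against 0.05, without oocytes G 4). Fry gave both sets an adjusted p of 0.0112, and camera adjusted p of 3.81e-34 and 1.78e-29, with an adjusted p of 0.143 for both with an estimated correlation. Without oocytes A 1 and 2 and oocytes G 4, a fit chosen after seeing the data, the unadjusted fry p were 0.0932 and 0.0833, and neither passes. Sfrp4, Hsd3b1 and Cyp11a1 belong to both sets. The 29, 10 and 10 tested genes lower in Aged+AF, higher in Aged+YF than in Aged+AF and higher in Aged+YF than in Young+YF had medians of 0.20, 0.22 and -0.29. Fry called the last of these lower in oocytes G (adjusted p = 0.0141, 1 of 10 genes higher; camera adjusted p = 0.138). These sets were chosen on the transplant libraries and share no library with the oocyte table.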

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

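No test in this part was chosen after its result was seen: in each group of 4 libraries, for library totals, marker sums and the genes named in the text, the highest or lowest library is listed where its gap to the nearest other exceeds the 95% limit of Dixon's test. For independent values with a normal spread, chance lists about 1 in 20 groups, which would be 14.9 of the 299 groups examined, and 34 were listed. Levels near the floor and genes that move together within a library do not meet this. A gene with counts in 1 library of a group and no counts in the others is always listed. The count of 34 against 14.9 therefore does not measure an excess of outlying libraries. Young+YF 2, Aged+YF 3 and oocytes A 4 were listed more often than the other libraries.

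Young+YF 2 stood above the other 3 libraries of its group in Hsd3b1 (6.04 CPM, others 0.13 to 0.179), Vcan (1.18, others at most 0.0747), Tpi1 (7.1, others 1.54 to 2.35), Ldha (3.51, others 0.346 to 0.485) and Scd1 (0.395, others at most 0.0373). Procr at 0.158 CPM and Sfrp4 at 0.197 CPM were found in Young+YF 2 and in no other library of the group. Young+YF 3 held 278 CPM of Cdc5l (others 374 to 393) and 36.7 of Amer1 (others 22.2 to 24.1), and Young+YF 4 held 34.2 CPM of Pigh (others 40.6 to 41.1).

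Among Aged+AF, library 1 was low in Eif2ak3 (4.56 CPM, others 8.43 to 8.8) and library 2 high in Glud1 (36.2, others 26.5 to 27.4). Aged+AF 3 was high in Gdf9 (9720 CPM, others 3050 to 3870) and Slc25a22 (23.9, others 3.35 to 4.74). Aged+AF 4 was high in Gcsh (72.5 CPM, others 20.8 to 29.5) and Hnrnpa0 (6.13, others 0.234 to 1.06).

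Aged+YF 3 was high in Hsd3b1 (4.01 CPM, others 0.061 to 0.221), Inhba (0.521, others at most 0.0305) and Olfm1 (159, others 118 to 124). Hs3st1 at 0.16 CPM, Crim1 at 0.361 and Scd1 at 0.0401 were found in Aged+YF 3 and in no other library of the group. Aged+YF 1 had 26.3% of its counts in its 100 largest genes (others 40.5 to 43.2%) and 4.85 CPM in the list of embryo activation genes (others 41 to 45). Aged+YF 4 had 279 CPM of leukocyte and macrophage genes (others 19.4 to 31.9), 0.398 of red cell genes (others at most 0.0401) and 1.81 of Slc38a2 (others at most 0.16).

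Oocytes A 4 was high in Gclm (152 CPM, others 23.7 to 35.8) and Rpl19 (24.8, others 13.4 to 14.6), and held the 0.0436 CPM of Akr1c18 and 0.0436 CPM of Slc38a2 seen in the group. Oocytes A 2 was high in Cyp11a1 (5.85 CPM, others 2.21 to 2.67) and oocytes G 1 in Slc38a2 (10.5 CPM, others 1.26 to 2.81).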

How the results depend on the processing

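Apart from the fits without Aged+AF 3 and 4, without oocytes A 1 and 2 (with and without oocytes G 4), which were chosen after seeing the data, the alternatives were chosen with the groups and tests. DESeq2 size factors left the counts at 303, 165, 14 and 44 for Aged+AF against Young+YF (282), Aged+YF against Aged+AF (159), Aged+YF against Young+YF (14) and oocytes G against A (45), and a fold limit of 2 changed none. Without a filter they were 266, 197, 19 and 80, and with 50 counts in 4 libraries 242, 32, 17 and 14. DESeq2's Wald test called 848, 720, 91 and 2061, limma-voom 274, 295, 32 and 16, and limma-voom with sample weights 1722, 676, 341 and 1333. Fits of only the groups compared called 651, 68 and 10. Without Aged+AF 3 and 4, the first counts were 19 and 8, and their list counts 5 and 7 in place of 13 and 16. Without oocytes A 1 and 2 there were 56 calls in oocytes G against A, and 19 without oocytes G 4 as well. With libraries left out in turn, the 4 counts ran from 5 to 438, 4 to 379, 0 to 53 and 3 to 2740, and list counts from 9 to 15, 14 to 17, 1 to 4 and 9 to 13. The genes moved back (88) were 92 with size factors, 23 with the stricter filter, 430 with the Wald test, 172 with limma-voom, 477 with weights, 6 without Aged+AF 3 and 4, 279 at an adjusted p under 0.1, 983 at an unadjusted p under 0.05, a median of 4.5 with the Aged+AF libraries divided, and 3 to 218 with aged libraries left out (2 to 40 with each Young+YF library left out, added after seeing the data). With an estimated correlation camera called 0 lists in all 4 comparisons (lowest adjusted p 0.329, 0.141, 0.923 and 0.176), and the transplant sets in the oocyte table, at medians of 1.99 and 2.09, had p of 0.057 and 0.0561. Their medians ran from 1.54 to 2.18 and from 1.58 to 2.31 with libraries left out, and the covariance of 0.958 from 0.847 to 1.35. Apart from the counts that fell with fewer libraries or genes, the cause was not tested. The direction of most calls turned in 2 comparisons. Oocytes G against A had 44 higher and 1 lower, but 710 and 1351 with the Wald test and 928 and 1812 without oocytes A 4. Aged+YF against Young+YF had 10 and 4, but 12 and 20 with limma-voom, 159 and 182 with weights and 20 and 33 without Aged+YF 4. Of the values of named genes under the alternatives, 5132 stayed on their side of the threshold, 303 crossed to pass and 764 crossed to fail, and none that was called changed sign.

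The replicate number as a block left 45, 18, 2 and 11 calls in the 4 comparisons and 9 genes moved back. Deviations of libraries that share a number correlated at 0.03, -0.03, 0.55 and 0.11 for numbers 1 to 4 of Aged+AF and Young+YF, at -0.21, -0.04, -0.4 and 0.25 for Aged+YF and Aged+AF, at -0.32, 0.09, -0.46 and 0.19 for Aged+YF and Young+YF, and at 0.15, 0.08, 0.2 and 0.03 for oocytes G and A, and 2, 0, 1 and 6 of 8 libraries lay closest to their own number. The numbers do not pair the transplant libraries; the oocyte libraries lean towards pairing (mean correlation 0.12, against -0.04 for other numbers), but not for every number, so they were not treated as pairs. The share of mitochondrial transcripts was not run, since no such gene is listed, and alternatives of the pseudocount do not apply to tests on counts. At 2-fold the fits called 12%, 2%, 6% and 0% of changed genes in the simulated counts, so that changes of that size can be missed.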

Other observations

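The explanations and splits tested in this part were chosen after the patterns were seen, except the thinning of libraries to equal depth and the removal of GC and length trends, whose outcomes were predicted before they were run. The tests of gene lists by camera and fry were fixed with the groups. Among the other lists, autophagy, glutathione, antioxidant and fatty acid genes leaned higher in Aged+AF than in Young+YF, with medians of 0.25, 0.48, 0.76 and 0.65 on the log2 scale (camera adjusted p = 0.0421, 0.016, 0.00321 and 0.021, and adjusted p = 0.387, 0.387, 0.339 and 0.339 with an estimated correlation). They had 2 of 28, 1 of 30, 1 of 24 and 1 of 26 members called. In Aged+YF against Aged+AF their medians were -0.41, -0.26, -0.54 and -0.33 (camera adjusted p = 0.00921, 0.0447, 0.00921 and 0.0236, and adjusted p = 0.315, 0.453, 0.315 and 0.315 with an estimated correlation). Spindle and epigenetic genes had medians of -0.14 and -0.22 in Aged+AF against Young+YF (camera adjusted p = 0.0436 each, and adjusted p = 0.382 and 0.387 with an estimated correlation). In Aged+YF against Aged+AF they had medians of 0.27 and 0.39 (camera adjusted p = 0.00921 and 0.0149, and adjusted p = 0.315 each with an estimated correlation), and meiotic cohesion genes one of 0.23 (camera adjusted p = 0.0219, and adjusted p = 0.453 with an estimated correlation). In oocytes G against A, autophagy, glutathione and cholesterol genes had medians of 0.72, 0.63 and 0.43 (camera adjusted p = 0.0015, 0.0037 and 0.0179, and adjusted p = 0.176, 0.245 and 0.245 with an estimated correlation), and fry called them at adjusted p of 0.00441, 0.0067 and 0.00647. Oocytes A 1 and 2 were lowest in each of these lists. Median glutathione levels were -0.96, -1.2, -0.27 and 0.25 in oocytes A 1 to 4 and 0.5, 0.47, 0.47 and 0.45 in oocytes G 1 to 4.

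The higher follicle cell genes of Aged+AF may come from differing amounts of follicle cells in the samples, or from a change within the cells sampled, and these data do not separate the 2; the samples are labelled ovary but rich in oocyte transcripts, and what they hold is not settled here. Within Aged+AF, 241 other genes called higher followed the 7 called granulosa, theca and luteal markers from library to library with a median correlation of 0.669, above the 95th percentile of 0.448 in 10000 random gene sets (median 0.349). The same median was 0.677 within Young+YF and 0.322 within Aged+YF. These genes and markers were chosen as higher in the same Aged+AF libraries and the random sets were not, so this comparison does not decide the source of the RNA. More cells of every type besides the oocyte would raise all 7 such lists. The sum of 1 of the 7, the immune genes, lay lower in every Aged+AF library than in every Young+YF library, while the other 6 had higher means. H2-Aa made up much of that immune sum, and edgeR called 0 of the 8 immune genes tested. More cells of every type are therefore not excluded. Mean totals were 26.5 M in Young+YF and 25.9 M in Aged+AF, and 235 of 248 genes stayed called with all libraries thinned to 24.5 M counts, a step too small to test depth on its own. Aged+AF and Young+YF differ in recipient age and in donor age at once, so their comparison does not separate these. The tests here do not tell a difference in cell makeup that follows from age or donor microbiota from one made in collection.

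Of the libraries labelled oocytes A, 1 and 2 stand apart on the first principal component of the oocyte table (77.9% of variance), at 121.5 and 125.1, where the other 6 libraries lie between -52.6 and -13.1. Their oocyte list sums, 20600 and 28600 CPM, were lower than the 64500 and 73700 of oocytes A 3 and 4, and the ratio of shares was 2.93 before and 2.92 after thinning to 17 M counts; thinning leaves shares unchanged on average, so this value does not bear on depth, which stays open. The sums of 6 of 7 lists of other cell types were lower too, and surface epithelium genes were higher at 77.3 and 67.7 CPM against 8.77 and 10. Such sums weigh abundant genes most. By the median level of members, granulosa genes alone were lower in both (-2.57 and -2.59, against -0.43 and -1.38 in oocytes A 3 and 4). Theca and luteal genes, for example, stood at -1.4 and -0.94 against -1.2 and -1.5. RNA of other cell types is therefore not excluded. Removal of trends on GC content and transcript length left a median log2 difference of -0.997 of an initial -1.69 in the oocyte list. By the rule written before the run, this remainder counted against a bias by GC content or length. A bootstrap interval of -1.4 to -0.22 was asked for after the value was seen. Its weaker end is too small for that verdict, so such a bias remains undecided. The labels give these 4 libraries the same group, so no biological explanation was tested.

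Oocytes G 4 lies close to a weighted sum of oocytes G 1, 2 and 3, with weights of 0.24, 0.386 and 0.36 and a residual of 1.3 times the counting variance over 11594 genes. The lowest value among 12 transplant libraries fitted in the same way was 15.29, and the 19 other libraries ran from 6.64 to 232.72. Hba-a1 had 6449, 0, 2 and 1567 counts in oocytes G 1 to 4, where the weighted sum gives 1548.5 for library 4, and Spp1 had 31986, 3296, 7691 and 12083, where it gives 11717.7. An independent sample is not expected to lie so close, and library 4 may hold material or reads of the other 3, which the labels do not say. No biological explanation was tested.

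The same counts were taken with the libraries of each comparison split in every other way into equal groups. For Aged+AF against Young+YF, 1 of 35 splits, the real one, reached 282 genes (highest other 0), and for Aged+YF against Aged+AF 1 of 35 reached 159 (highest other 2). For oocytes G against A, 1 of 35 reached 45 (highest other 0), but these splits treat oocytes G 4 as independent of the other 3. Without it, 2 of 35 splits of the 7 libraries reached the 5 genes then called, so chance is not excluded for this count. The split of oocytes A 1, 2 and 3 against the rest called 1408, which points to a structure within oocytes A. Compared with single libraries, oocytes A 4 lay nearer to oocytes G 3 than to oocytes A 3, with residuals of 10.33 and 24.33 times the counting variance. Its residuals with oocytes G 1 and 2 were 34.48 and 23.81, and with oocytes A 1 and 2 they were 156.4 and 187.34. Of the aged libraries, 1 of 70 labellings reached 88 genes moved back (highest other 4). For Aged+YF against Young+YF, 2 of 35 splits reached 14, and the split of Young+YF 1 and 2 with Aged+YF 3 and 4 against the rest called 29, which points to a structure among these libraries that is not their group. On the first principal component of the transplant libraries (29.2% of variance), Aged+YF 1 to 4 lay at -92.5, -23.2, 21.9 and 45.4. Young+YF lay between -33.1 and 6.3 and Aged+AF between -40.8 and 39.7, so this component did not follow the groups. Aged+YF 1 also left the highest residual from its group, 232.72 times the counting variance. The transplant sets in the oocyte table reached their medians of 1.99 and 2.09 in 1 of 35 splits each (highest other 1.57 and 1.61), and without oocytes G 4 reached 1.95 and 2.07 in 1 of 35 each (highest other 1.8 and 2.04). The counts of 13, 16, 1 and 10 lists were reached by 4, 2, 35 and 2 of 35 splits (highest other 16, 16, 10 and 10), so chance splits of the libraries can call as many lists.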
